A study of Monascus purpureus with 6 samples.

How the data were processed

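RNA was measured in 6 libraries of Monascus purpureus mycelia, 3 control and 3 metal-ion, all from day 1. Per the labels' protocols, RNA was taken with TRIzol, enriched for mRNA, fragmented and made into cDNA libraries with a NEBNext Ultra kit that does not mark the strand, and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, TopHat2 was used, with no version given. The counting tool, the genome build and the annotation were not given in the sources used here. The authors deposited a table of whole-number counts per gene and a table of FPKM values, which are scaled to gene length and library size, for the same 9836 genes and 6 libraries. Dividing the deposited counts by the deposited FPKM gave 1 implied length per gene, with a median spread between libraries of 0.464%. Columns were matched to samples through the sample descriptions, and groups and replicate numbers came from the sample titles.

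Of the 9836 gene identifiers, 9151 were MAP00 locus tags and 685 were identifiers of genes that the authors added. All 9151 locus tags matched the annotation of assembly ASM2599979v1 (strain KUPM5), which was used only for symbols, for the order of neighbouring genes and for which gene models overlap a neighbour. Since no source names the authors' build, no coordinates are given. A symbol other than the locus tag was paired with 882 genes, of which 872 were tested, so most genes are named here by locus tag and their products were not analysed here.

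The comparison used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the default low-count filter, a two-sided test and Benjamini-Hochberg adjustment over the tested genes. The filter kept 9048 genes, which held 99.9916% of the counts; 788 genes were left out, 138 of them with no counts in any library. A gene was called changed at an adjusted p under 0.05. Levels are given as CPM, counts scaled to the library total with the TMM factor, with the SD over 3 libraries. Log2 fold changes are metal-ion over control, with a standard error taken from the fold change and its F statistic. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Counts differed between replicates by more than sampling noise in every pair, with a chi-square per degree of freedom of 14.3 to 21.7 between control libraries and 36.7 to 118 between metal-ion libraries, so each library was counted as 1 replicate. The common biological coefficient of variation was 0.148.

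The tests, the alternatives, 28 gene lists defined by name patterns and the rule for named genes were fixed before the data were examined. Only symbols could be matched: 23 of the 28 lists matched no symbol, among them pigment synthesis, citrinin synthesis, zinc transport and magnesium transport, and 3 matched 1 to 4 symbols. The 3 were ethanol fermentation (ADH1), fatty acid synthase (FAS1) and DNA replication (MCM2, MCM5 and MCM7). The remaining 2, chaperones and ergosterol synthesis, were tested. A further 24 lists were written from the symbols in the annotation, after the tables had been opened and before any test was run. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01 and adjusted over the 26 lists. Members that passed are counted over all tested genes and also adjusted over the list alone.

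Named genes are the 5 that rose and the 5 that fell most, among called genes with a mean of at least 10 CPM and no overlap between groups. Up to 2 called members in each direction of each list with a mean of at least 5 CPM were added, with the members of the ethanol list whether or not they passed. Every gene with a symbol that changed at least 2-fold was added after the values were seen, as were the neighbouring genes described as blocks.

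On simulated data with the means, depths and dispersions of the 9048 genes in this comparison, the test recovered 44% of 50 genes changed 1.5-fold, 76% of 50 changed 2-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold. Of its 162 calls, 4 (2.47%) were false. The simulation drew each gene independently and changed far fewer genes than the 1084 called in the data. These percentages may therefore differ for the real comparison. Alternatives covered other scalings and filters, gene length, the replicate number as a block, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other list tests and the removal of each library. Totals and shares of counts were compared with exact two-sided permutation tests, for which 3 against 3 libraries allow no p under 0.1.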

Results

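Gene expression was profiled by RNA sequencing in mycelia of Monascus purpureus, a filamentous fungus that makes red pigments and ethanol, using wild-type strain MP2022. There were 3 libraries of control mycelia and 3 of mycelia under a metal ion condition that the titles call optimized, all at day 1. The metal-ion label gives 0.0 g/L of hydrated zinc sulphate and 2.5 g/L of hydrated magnesium sulphate. The control label names 2.0 g/L and 1.0 g/L of these salts but calls the mycelia untreated with them, which leaves open whether the control medium held them. The comparison belongs to a search for the balance of zinc and magnesium that favours ethanol and pigment together. Control libraries held 33638067, 36537672 and 33706761 counts and metal-ion libraries 35357043, 38927910 and 35314601, in order of replicate number (exact two-sided permutation p = 0.3, 3 libraries per group). The 10 most abundant genes took 14.2 ± 0.310% of counts in control and 13.4 ± 0.931% in metal-ion libraries (SD, n = 3; exact permutation p = 0.3).

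Metal-ion mycelia carried far more mRNA of a few sets of neighbouring genes, of the superoxide dismutase gene SOD2 and of the inositol phosphate synthase gene RINO2 than control mycelia. Of 56 tested ribosomal protein genes 48 fell, and of 44 ribosome assembly genes 20, each of these by less than 2-fold (list tests at adjusted p = 7.35e-21 and 8.90e-12 with camera, and both at adjusted p = 0.705 with an estimated correlation). Without any one library other than metal-ion replicate 2, 0 of the 56 ribosomal protein genes (53 to 55 at an unadjusted p under 0.05) and 2 to 4 of the 44 assembly genes passed in edgeR. Among genes of amino acid synthesis, MET26 and LEU2A rose most. Of 9048 tested genes, 1084 (12%) changed, 603 up and 481 down, and 256 changed at least 2-fold, 204 up and 52 down (edgeR quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap in 33.3% of tested genes, where chance gives 10% for each gene. Genes vary together, so how far this share departs from chance was not tested. They did not overlap in 1075 of the 1084 called genes either, but a test of the same libraries had picked those genes.

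**Figure D1:**
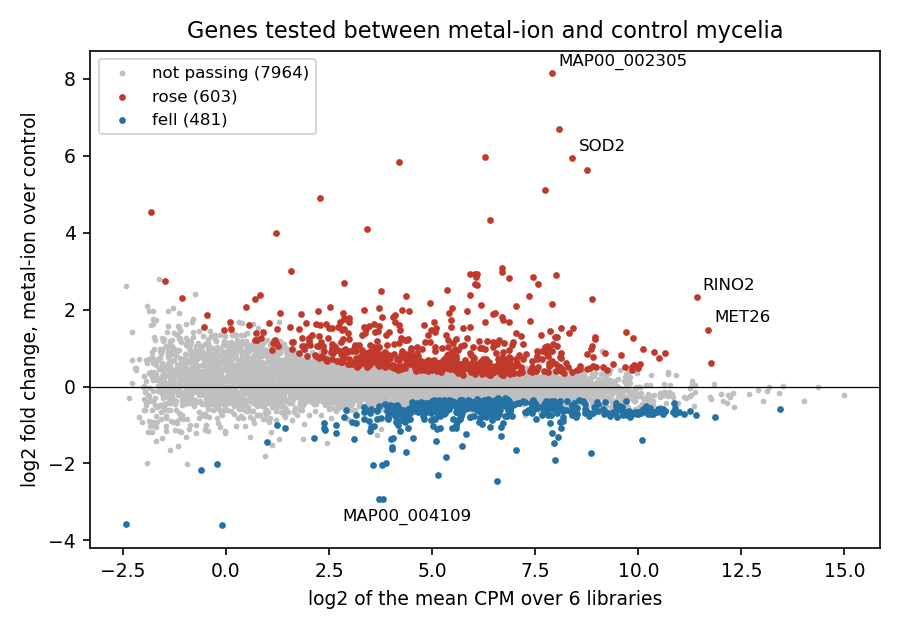
Each point is a tested gene, with the log2 of its mean CPM over 6 libraries on the x axis and its log2 fold change, metal-ion over control, on the y axis. Red points are the 603 genes that rose, blue points the 481 that fell and grey points the 7964 that did not pass; the strongest rises reach a log2 fold change of 8.14, while most falls are smaller than 2-fold.

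The number of calls changed with the libraries kept. Leaving out 1 library also leaves fewer to test, so a lost call alone does not show that a gene rested on that library. The number of calls was 362, 348 and 451 without control replicate 1, 2 or 3, and 472 and 446 without metal-ion replicate 1 or 3. Without metal-ion replicate 2 it was 2829, 1080 of them among the 1084, and calls of at least 2-fold went from 256 to 415. On the first principal component of log2 CPM, with 48.6% of the variance, that replicate scored 9.79, between control libraries at -27.9 to -21.3 and the other metal-ion libraries at 30.4 and 31.8. Scaling by total counts alone moved the median log2 fold change of all genes from 0.03 to 0.14 and the split of calls to 860 up and 344 down, and limma on log2(FPKM + 1) gave 794 up and 350 down. Of the 46 called genes named by rule here, 24 lost their call without at least 1 library. The 22 that passed under every alternative were SOD2, RINO2, AOX1_3, AAD14, MDR1_2, MET26, ERG13_2, LEU2A, MPL4, MPL6, FUS6, ATM1, MAP00_002305, MAP00_002306, MAP00_003524 and MAP00_004002, which rose, and AAH1, NOG2, MAP00_002706, MAP00_004108, MAP00_004109 and MAP00_006770, which fell.

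The steepest rises came from neighbouring genes. MAP00_002305 went from 1.70 ± 0.474 CPM in control to 480.0 ± 73.2 CPM in metal-ion mycelia (SD, n = 3), a log2 fold change of 8.14 ± 0.22 (SE; edgeR adjusted p = 9.57e-09). The next 3 genes in the annotation rose with it, MAP00_002306 by 5.96, MAP00_002307 by 5.64 and MAP00_002308 by 5.11 on the log2 scale. SOD2 (MAP00_003523), named for a superoxide dismutase that removes superoxide radicals, rose from 10.9 ± 2.76 to 667 ± 96.7 CPM, a log2 fold change of 5.94 ± 0.21 (adjusted p = 8.81e-08). Its neighbours MAP00_003524 and MAP00_003525 rose by 6.70 and 1.20. MAP00_004002 rose by 5.85 ± 0.42 (adjusted p = 9.35e-06), but its model overlaps that of a neighbour, and without strand information their reads cannot be told apart. Its control libraries held 36, 7 and 19 counts, and its log2 fold change was 6.52 without control replicate 1 and 5.40 without control replicate 2.

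The widest set of neighbours that rose ran from MAP00_007450 to MAP00_007472. Of its 23 annotated genes 22 were tested, 21 rose and 20 rose at least 2-fold, with a median log2 fold change of 2.45. MAP00_007467 rose most, from 23.4 ± 5.05 to 186 ± 18.1 CPM (log2 fold change 2.99 ± 0.15, adjusted p = 1.30e-06). MAP00_007458 was the most abundant in metal-ion mycelia, at 787 ± 153 CPM against 161 ± 26.5 CPM in control. In control MAP00_007460 stood higher, at 169 ± 24.7 CPM. MAP00_007464 did not pass (log2 fold change 0.23 ± 0.18, adjusted p = 0.441), and MAP00_007465 was not tested. The genes on either side, CPR6 (MAP00_007449) and MAP00_007473, had log2 fold changes of -0.27 and -0.14 and did not pass. The sets of neighbours were singled out after their values were seen. In this one, 20 or 21 genes rose whichever library was left out.

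**Figure D2:**
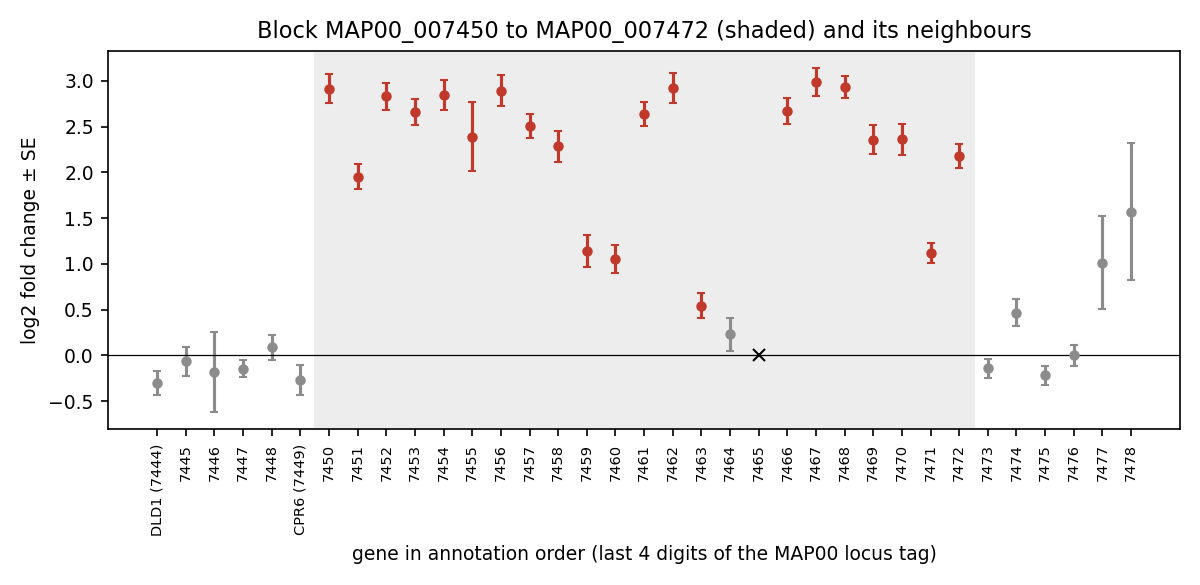
Log2 fold change, metal-ion over control, with its standard error (y axis) for the genes from MAP00_007450 to MAP00_007472 (shaded) and 6 neighbours on each side, in annotation order (x axis). Red points rose, grey points did not pass and the cross marks the untested MAP00_007465; the 21 genes that rose span log2 fold changes of 0.54 to 2.99.

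Among genes with a symbol, RINO2 (MAP00_003136), named for inositol-3-phosphate synthase, rose from 911 ± 4.08 to 4549 ± 235 CPM (log2 fold change 2.32 ± 0.12, edgeR adjusted p = 1.10e-06). AOX1_3 rose by 1.73 ± 0.15 on the log2 scale, AAD14, named for an aryl-alcohol dehydrogenase, by 1.54 ± 0.13 and MDR1_2, named for a multidrug transporter, by 1.52 ± 0.13. ERG13_2, named for the enzyme that makes hydroxymethylglutaryl-CoA for sterol synthesis, rose from 178 ± 7.11 to 464 ± 30.9 CPM. ERG13_1 (MAP00_002322), another gene named for this enzyme, did not pass (log2 fold change -0.21 ± 0.13, edgeR adjusted p = 0.304). MPL6, AMT1, MPL4 and FUS6 rose by 1.09, 1.06, 1.02 and 1.01. AMT1, at 3.10 to 6.46 CPM on average, passed in only 1 of the 6 fits without a library, the one without metal-ion replicate 2. ALV1 had a log2 fold change of -1.54 ± 0.33, MCCC2 of -1.34 ± 0.32 and SID4 of -1.03 ± 0.22, and all 3 fell. ALV1 lost its call without control replicate 1 or 2 or metal-ion replicate 1 or 3 and had a log2 fold change of -2.15 without metal-ion replicate 2, MCCC2 without any one control replicate or metal-ion replicate 1, and SID4 without control replicate 1 or 3 or metal-ion replicate 3. Suffixes such as _3 and _2 mark genes that share a symbol in the annotation. Whether the authors' counting divided reads between such genes was not tested.

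Among called genes with a mean of at least 10 CPM and no overlap between groups, those that fell most were the neighbours MAP00_004109 and MAP00_004108, with log2 fold changes of -2.94 ± 0.24 and -2.92 ± 0.18 (edgeR adjusted p = 2.41e-05 and 4.29e-06). MAP00_004109 went from 25.0 ± 6.53 to 3.26 ± 0.739 CPM. MAP00_005124, MAP00_006770 and MAP00_002706 followed at -2.46 ± 0.51, -2.29 ± 0.20 and -2.05 ± 0.32. MAP00_006770 overlaps a neighbour, so its reads are uncertain. MAP00_005124 lost its call without control replicate 1 or 2 or metal-ion replicate 3 (highest adjusted p = 0.0672). Without metal-ion replicate 2 the log2 fold change of MAP00_005124 was -3.56 and that of MAP00_002706 was -2.65.

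The ethanol list held 1 gene, ADH1 (MAP00_001261), named for alcohol dehydrogenase. It was among the abundant genes, with 9519 ± 409 CPM in control and 7286 ± 945 CPM in metal-ion mycelia, and did not pass (log2 fold change -0.39 ± 0.13, edgeR adjusted p = 0.0899), lower in 3 of 3 metal-ion libraries. DESeq2 and the fit without metal-ion replicate 2 called it (adjusted p = 0.00741 and 0.00865), and scaling by abundance turned its sign (log2 fold change 0.07). FAS1, named for fatty acid synthase, stood at 701 ± 27.1 and 687 ± 120 CPM and did not pass (log2 fold change -0.03 ± 0.13, adjusted p = 0.910). MCM2, MCM5 and MCM7, of the replicative helicase, did not pass either, at log2 fold changes of -0.16, -0.24 and -0.23. Genes for pigment synthesis and for transport of zinc or magnesium were not analysed here as groups, since no symbol matched their patterns.

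Cytosolic ribosomal protein genes formed the broadest group that fell. Of 56 tested, 48 fell and 0 rose, against 55 that fell adjusted over the list alone, and the median log2 fold change was -0.67 (camera adjusted p = 7.35e-21, adjusted p = 0.705 with an estimated correlation). For 0 that rose, edgeR at an unadjusted p under 0.05, DESeq2 and limma on FPKM also gave 0. RPS20 went from 902 ± 60.9 to 519 ± 179 CPM (log2 fold change -0.80 ± 0.20, edgeR adjusted p = 0.0306), and RPL28, which overlaps a neighbour, had a log2 fold change of -0.78 ± 0.21. The 56 genes took 6.40, 6.95 and 6.36% of counts in control libraries and 3.93, 5.58 and 3.88% in metal-ion libraries (exact permutation p = 0.1, the smallest possible). Of the metal-ion libraries, replicate 2 was nearest to control. Without control replicate 1, 2 or 3 or metal-ion replicate 1 or 3, 0 of the 56 passed in edgeR, while 53 to 55 had an unadjusted p under 0.05 and the median stayed between -0.70 and -0.55; without metal-ion replicate 2, 55 fell with a median of -0.94.

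Of 44 ribosome assembly genes, 20 fell (34 adjusted over the list alone) and the median log2 fold change was -0.48 (camera adjusted p = 8.90e-12, adjusted p = 0.705 with an estimated correlation). NOG2, named for a nucleolar GTPase, went from 90.6 ± 0.246 to 51.5 ± 10.7 CPM (log2 fold change -0.82 ± 0.14), and YTM1 had a log2 fold change of -0.69 ± 0.18. Of 19 translation factors, 7 fell (12 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 4.22e-05, adjusted p = 0.705 with an estimated correlation). Among them were PAB1_1, named for poly(A)-binding protein, at -0.67 ± 0.14, and TIF34, a subunit of an initiation factor, at -0.62 ± 0.14. PAB1_2, another gene named for poly(A)-binding protein, did not pass, at -0.07 ± 0.09 (edgeR adjusted p = 0.653). Without metal-ion replicate 2, 39 assembly genes and 14 translation factors fell, and without any other single library 2 to 4 and 0 or 1.

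Of 17 genes of nucleotide metabolism, 5 fell (8 fell and 1 rose adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00430, adjusted p = 0.705 with an estimated correlation). AAH1, named for adenine deaminase, had a log2 fold change of -0.96 ± 0.12 and GUA1, named for GMP synthase, of -0.62 ± 0.14. Without metal-ion replicate 2, 10 of the 17 fell and 2 rose, and without any other single library 1 fell. The secretory pathway had 3 of 12 genes that fell (6 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.00230, adjusted p = 0.705 with an estimated correlation). They included ERV14 and RER1, at -0.55 and -0.49. The cytosolic chaperonin had 1 of 7 genes that fell, CCT1 at -0.44 (7 adjusted over the list alone; camera adjusted p = 0.00491, adjusted p = 0.705 with an estimated correlation). Mitochondrial protein import had 1 of 11, TIM17 at -0.38 (6 adjusted over the list alone; camera adjusted p = 0.00558, adjusted p = 0.705 with an estimated correlation). In these 3 lists 8, 7 and 10 genes fell without metal-ion replicate 2, and at most 1, 0 and 0 without any other single library. The respiratory chain and ATP synthase list passed with a median of -0.14 (camera adjusted p = 0.0379, adjusted p = 0.705 with an estimated correlation) although 0 of its 21 genes did in edgeR or adjusted over the list alone, where 5 had an unadjusted p under 0.05, DESeq2 called 4 and limma on FPKM 0. That list lost its call without control replicate 2, metal-ion replicate 1 or metal-ion replicate 3 (adjusted p = 0.131, 0.302 and 0.170), and with an offset for gene length (adjusted p = 0.0505).

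Amino acid synthesis was the broadest group that rose. Of its 36 genes, 9 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 0.21 (camera adjusted p = 0.00230, adjusted p = 0.705 with an estimated correlation). MET26 (MAP00_001884), named for methionine synthase, went from 1758 ± 134 to 4886 ± 808 CPM (log2 fold change 1.48 ± 0.15, edgeR adjusted p = 0.000121). LEU2A, of leucine synthesis, went from 297 ± 6.56 to 699 ± 105 CPM (log2 fold change 1.23 ± 0.13), and overlaps a neighbour. CYS3, named for cystathionine gamma-lyase, fell by 0.37 on the log2 scale, and passed in 1 of the 6 fits without a library. Without metal-ion replicate 2, 20 of the 36 rose and 3 fell, and without control replicate 1 or 2, 3 and 4 rose.

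In the antioxidant list 2 of 11 genes rose, also adjusted over the list alone, SOD2 and PRX1, the latter named for a peroxiredoxin (log2 fold change 0.65 ± 0.12). The list passed (camera adjusted p = 0.00558, adjusted p = 0.705 with an estimated correlation) with a mean of 0.60 but a median of 0.04, and did not pass without metal-ion replicate 2 or with camera on log2(FPKM + 1) (adjusted p = 0.0803 and 0.145). In iron-sulfur cluster assembly 2 of 9 genes rose, also adjusted over the list alone: ATM1, named for a mitochondrial exporter, by 0.80 ± 0.12 and NAR1 by 0.59 ± 0.10. That list had a median of -0.02 and a mean of 0.03 and did not pass (camera adjusted p = 0.476). Of 11 secreted and vacuolar peptidases, ALP2 and PEP2 rose by 0.56 and 0.50 and ASPERGILLOPEPSIN2 fell, at -1.15 (3 and 1 adjusted over the list alone; camera adjusted p = 0.309).

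**Figure D3:**
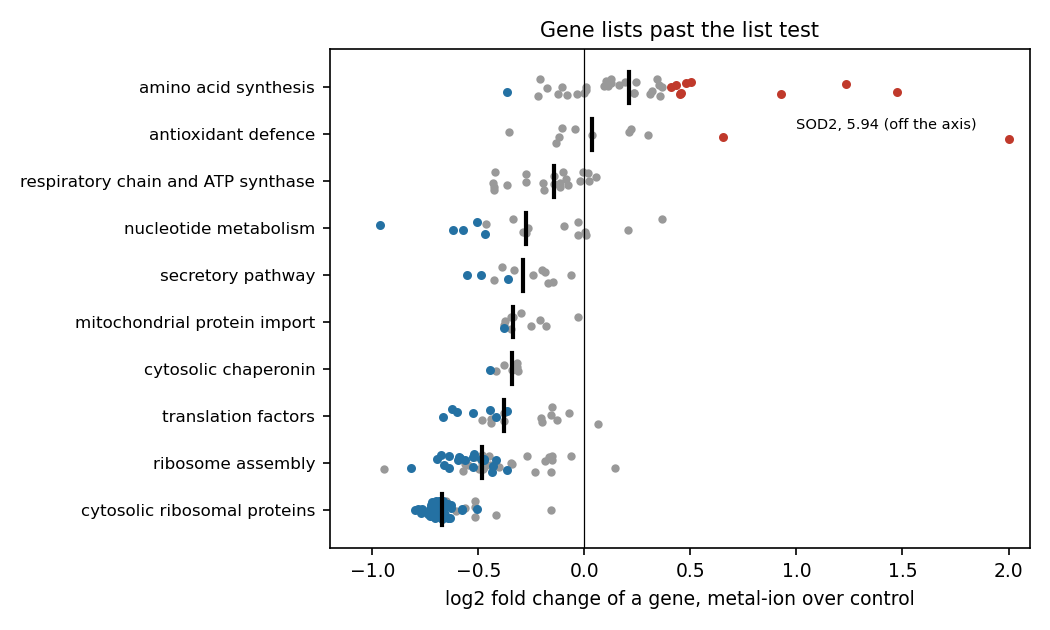
Log2 fold change, metal-ion over control (x axis), of each tested gene in the 10 lists (y axis) that passed camera at its preset correlation, of which 0 passed with an estimated correlation (adjusted p = 0.705 for each); red genes rose, blue genes fell, grey genes did not pass and black bars are list medians. Ribosomal protein genes lie around a median of -0.67, and SOD2, at 5.94, is drawn at the right edge.

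The 7 heat shock genes gave a median of -0.25 and did not pass (camera adjusted p = 0.102), but did without metal-ion replicate 2 (adjusted p = 0.000549) and with camera on log2(FPKM + 1) (adjusted p = 0.0145). None was called by edgeR or adjusted over the list alone, while 3 had an unadjusted p under 0.05, DESeq2 called 2 and limma on FPKM 0. HSP60 and HSP10 had the lowest values, at log2 fold changes of -0.48 ± 0.17 and -0.46 ± 0.16 (edgeR adjusted p = 0.0976 and 0.0965). In ergosterol synthesis 1 of 5 genes rose, ERG13_2 by 1.38 ± 0.10 (1 rose and 1 fell adjusted over the list alone). Its median of -0.19 differs in sign from its mean of 0.10 and from the upward direction of the test (camera adjusted p = 0.493). The wider list of 9 sterol and isoprenoid genes gave -0.17, 0.05 and an upward test likewise (camera adjusted p = 0.758).

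The remaining 11 lists did not pass. Camera adjusted p was 0.0895 for the proteasome, 0.0809 for pyruvate dehydrogenase and the TCA cycle, 0.0992 for splicing, 0.157 for DNA replication and histones, 0.157 for the cell wall and 0.246 for autophagy. It was 0.254 for N-glycosylation and for glycogen, trehalose, polyol and sugar metabolism, 0.429 for ubiquitin conjugation, 0.476 for cytochrome oxidase assembly and 0.493 for the vacuolar ATPase. Without metal-ion replicate 2, the proteasome, pyruvate dehydrogenase and the TCA cycle, splicing and autophagy passed (camera adjusted p = 0.0246, 0.00377, 0.0376 and 0.0363). Of these, autophagy passed upward and the others downward. Pyruvate dehydrogenase and the TCA cycle also passed with camera on log2(FPKM + 1) (adjusted p = 0.0145). Members that changed were DPM1 of N-glycosylation and GLD2 of sugar metabolism, at log2 fold changes of -0.47 and -0.38, and CTF18 of DNA replication, which rose by 0.79 although its groups overlapped.

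**Figure D4:**
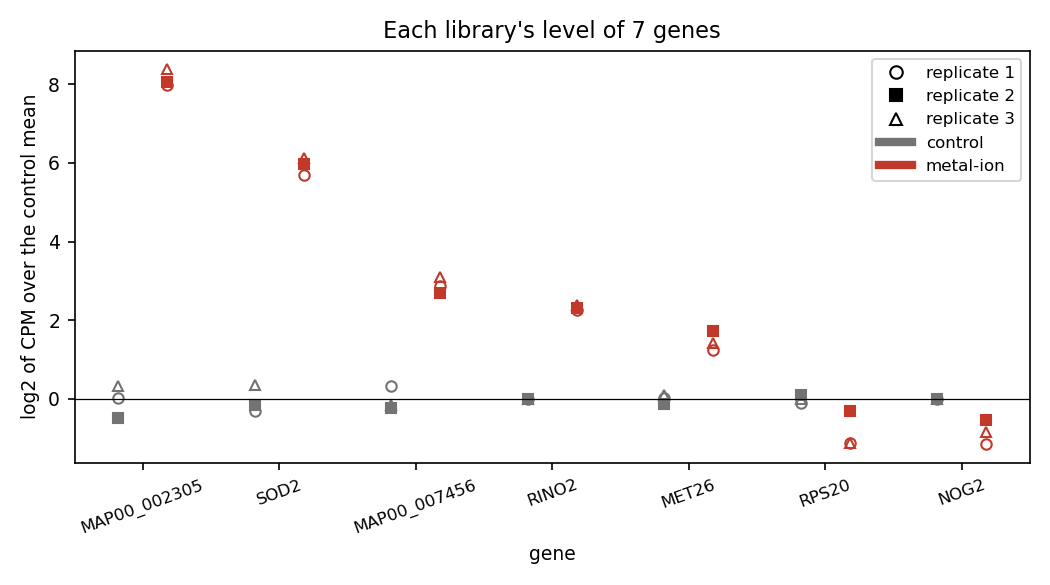
Log2 of the CPM of 7 genes in each library over the control mean (y axis), with genes on the x axis, control libraries in grey, metal-ion libraries in red and a marker shape per replicate. SOD2 and RINO2 lie far above control in each of the 3 metal-ion libraries, while RPS20 in metal-ion replicate 2 lies between the groups.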

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

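The settings for ribosomal protein genes and for neighbouring genes, and the length offset in the list tests, were chosen after the results were seen; the others were fixed beforehand. Calls ranged from 348 to 2829 when each library was left out, calls of at least 2-fold from 194 to 415 and ribosomal protein genes that fell from 0 to 55. Limma on log2(FPKM + 1) without a filter called 658 genes and 1 ribosomal protein gene, and the cause was not tested. Lists that passed numbered 0 with an estimated correlation and 3 with fry, which tests each list on its own: amino acid synthesis and peptidases (both adjusted p = 0.0488) and iron-sulfur assembly (0.0456). Heat shock genes and pyruvate dehydrogenase and the TCA cycle passed with camera on log2(FPKM + 1) (both adjusted p = 0.0145). Heat shock genes ranged from 0.000549 to 0.409 without single libraries, and pyruvate dehydrogenase and the TCA cycle from 0.00377 to 0.290. On log2(FPKM + 1) the list direction reversed for ergosterol synthesis (adjusted p = 0.787) and for sterol and isoprenoid synthesis (0.775). ADH1 reversed to 0.0744 with scaling by abundance. The cause of these was not tested. The 100 most abundant genes gave a difference in share of -2.42 percentage points, against -0.813 for the 10 most abundant. For named genes, 717 values kept direction and side of the threshold, 125 lost the call, 2 gained it and 1 reversed. Of the 46 named genes called, 22 passed under every alternative, 16 that rose and 6 that fell, and 24 lost their call without at least 1 library. With the replicate number as a block the number of calls was 1365, and 55 of 56 ribosomal protein genes fell. The labels do not say whether equal numbers pair libraries. Correlations of their deviations were 0.0155, 0.141 and 0.0330 for equal numbers, and not every library correlated best with its own. The value of 0.141, for replicate 2, was the highest of any pair. Deviations cancel out within a group, so these correlations cannot rule out pairing. With this depth and 3 libraries per group, 44% of simulated 1.5-fold changes were found.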

Other observations

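The genes of the next paragraph, and all tests here except those of library depth, gene length, library scaling and other splits, were chosen after the results were seen.

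Further single genes that changed were picked by symbol or by place, and were not tested for enrichment as a set. AGNPKS1, FDH1 and ICL1 were picked by symbol too and did not pass (edgeR adjusted p = 0.9046, 0.1675 and 0.1446). AGNPKS1 stood at only 0.29 CPM in control and 0.33 CPM in metal-ion mycelia. MET3, named for ATP sulfurylase, rose by 0.93 ± 0.14 on the log2 scale, MET2, of homoserine acetylation, by 0.48 ± 0.09 and ETH1, named for S-adenosylmethionine synthetase, by 0.98 ± 0.17 (edgeR adjusted p = 0.00283, 0.00663 and 0.00472). SAH1, named for adenosylhomocysteinase, rose by 0.59 ± 0.16 and CHO2, of phospholipid methylation, by 0.48 ± 0.13, and both lost their call in 4 of the 6 fits without a library, and MET2 in 1. CYS3 fell (log2 fold change -0.37 ± 0.10, adjusted p = 0.0344), and passed in 1 of those fits. MPL1, MPL2, MPL4, MPL6 and MPL7, which lie between MAP00_006373 and MAP00_006379, all rose, by 0.72, 0.91, 1.02, 1.09 and 0.93, from control levels of 16.4 CPM or less, but MPL1 and MPL2 passed in only 1 and 2 of those 6 fits. FUS6 lay in a run of 8 genes that rose, MAP00_005935 to MAP00_005942, with a median of 0.91. ALV1 lay in a run of 5 that fell, MAP00_005120 to MAP00_005124, with a median of -1.24.

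The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1084 genes, 256 of them at least 2-fold, and was the 1 split of 10 that called as many. The highest other split called 1 gene. Every other split mixes the groups, which turns any difference between them into spread within a side. Few calls there therefore follow from any such difference and do not tell its cause.

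Metal-ion replicate 2 lay between the groups, and 3 technical explanations were tested. Against library depth, its place on the first component (control 0, other metal-ion libraries 1) was 0.614 after thinning to the smallest total and 0.613 before; against a control library under a wrong label, it showed a median share of 0.839 (quartiles 0.51 to 1.07) of the change in 179 genes with a mean of at least 5 CPM that rose at least 2-fold without it (0.712, quartiles 0.346 to 1.01, over 287 genes with no minimum). Control RNA mixed into it would give all genes a like share, but 508 genes over the same minimum that fell at least 1.5-fold gave 0.389 (quartiles 0.29 to 0.572), a difference of 0.449 (95% resampling interval 0.362 to 0.522, with genes taken as independent), which argues against mixing alone. The first criterion, quartile ranges that do not overlap, was not met and the interval replaced it after that was seen, so this evidence is weaker, and mixing as part of the difference stays open. A difference in the state of that culture may remain, which no label describes and no test addressed.

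The fall of ribosomal protein genes was weighed against length, scaling and the weight of single libraries. These genes are short, with a median implied length of 698 bases against 1575 for all tested genes, but an offset for length left the median at -0.692 (quartiles -0.721 to -0.66), against -0.671 before. Relative to the median of all genes, the highest median under any scaling was -0.451, with scaling by abundance. A factor per library moves all genes alike and cancels from that difference, so it cannot test such factors. Without the subtraction the list median was -0.671 with TMM, -0.575 with total counts alone and -0.444 with scaling by abundance. In metal-ion replicate 2 alone the median log2 ratio to the controls was -0.276, against -0.972 and -0.87 in replicates 1 and 3. For each control against the other 2 it was -0.0795 to 0.145. In replicate 2, 55 of the 56 genes lay below all 3 controls, and the 56 showed a median share of 0.373 of the change (quartiles 0.323 to 0.399). The ratio of -0.276 lay between the bounds set for this test, so it decided neither way. These genes also moved as one between controls, since control replicate 2 lay above both other controls in 54 of the 56, and 1 library against 3 allows no one-sided permutation p under 0.25, so a fall in replicates 1 and 3 alone cannot be told apart from a smaller fall in replicate 2, and the metal ion condition itself stays open as the biological difference between the groups, untested.

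The run of neighbours that rose could be a chance of gene order or reads spilling from 1 strong gene. In 10000 shuffled orders, 0 had a run of rising genes as long as the 14 observed (highest 7; permutation p = 1e-04, the smallest possible). Of the 22 tested genes from MAP00_007450 to MAP00_007472, 13 reached at least 10% of the highest FPKM, 693 in MAP00_007458. This argues against spill from that gene alone as the source of the whole set. Spill between adjacent genes was not tested. MAP00_007455, which counts among those that rose, had 2.97 CPM in metal-ion libraries, beside MAP00_007454 at 308 CPM and MAP00_007456 at 452 CPM. The set holds genes with implied lengths of 8570, 6382 and 6982 bases (MAP00_007450, MAP00_007461 and MAP00_007462). A candidate explanation is a cluster of genes regulated together; their products and a change in copy number were not analysed here.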
